A study of Mus musculus with 8 samples.

How the data were processed

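Poly(A) RNA of perfused livers from C57BL/6N mice was made into stranded libraries, per the labels' protocols, 4 for WT and 4 for CAPZ_KO. The deposited values are raw read counts per gene symbol, 1 column per library, not scaled to library size. Per the submitters' processing notes, bcl2fastq, STAR 2.5.3a, featureCounts, R 3.3.1 and edgeR were used with the genome build mm10, with no role or order given. The gene annotation, the strand setting and the handling of reads that match several genes are not given in the sources used here. Reads from overlapping genes, from genes on opposite strands and from near-identical copies can therefore be divided in ways that are unknown. Among named genes, exons of Capza1, Acadvl, Acss2, Ahsg, Alas2, Cebpb, Col4a1, Elovl3, Fn1, Gls2, Glul, Hk1, Igf2, Il1b, Myl12a, Pklr and Slc51b overlap exons of a gene on the opposite strand, and exons of Serpina3k, Cyp2c29 and Myl12a overlap those of a related gene on the same strand. The table held 24421 symbols, of which 6905 had no count. Positions were taken from GENCODE vM21 on GRCm38, the assembly that mm10 also names, in which 95.7% of the symbols were found.

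Genes were kept by the filterByExpr function of edgeR 4.0.16 (minimum count 10, minimum total count 15), which left 12985 for testing and removed 0.0451% to 0.109% of the counts of a library. Counts were scaled by TMM, whose factors were 0.774 to 0.847 in WT and 1.18 to 1.33 in CAPZ_KO, and tested by the edgeR quasi-likelihood test with robust dispersion, all 8 libraries and no covariate, with Benjamini-Hochberg adjustment and a threshold of 0.05 (R 4.3.3, limma 3.58.1). Every adjusted p given for a gene comes from edgeR unless another tool is named. Normalised values are CPM, read counts scaled to library size after TMM. The common biological coefficient of variation was 24.9%. Capzb was also compared by an exact two-sided permutation test of log2(CPM + 1). Intervals of 95% for a ratio of counts cover counting error only.

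The 26 gene lists and 10 marker lists tested, with 1 more marker list too short to test, were written from textbook knowledge before the data were examined. Each was tested by camera in limma on voom values with a preset correlation of 0.01, adjusted over the 36 lists. With that setting 17 lists were higher and 12 lower. With an estimated correlation 0 lists passed an adjusted p under 0.05, and by fry, which asks whether the genes of a list move on balance in 1 direction, 29 did, with glycolysis among them and the male-predominant list not. Named genes were set by a rule fixed before the data were examined. It took the capping protein genes, the 10 genes with the largest change per direction (adjusted p under 0.05, at least 2-fold, mean CPM of at least 5, groups apart, no gene model symbols), up to 4 members with the smallest p of each list, and the 5 genes with the largest mean CPM per group. Genes outside it are said to be chosen after their values were seen. A few genes and 1 gene family are not reported here.

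The gene test was tested on simulated counts for the 12985 genes of CAPZ_KO against WT, with 50 genes changed by each of 4 folds. It called 4 of 12785 unchanged genes and recovered 3 of 50 changed by 1.5-fold, 22 of 50 by 2-fold, 44 of 50 by 4-fold and 48 of 50 by 8-fold. The list test called 2 of 2 shifted lists and 0 of 20 others. Simulated genes were drawn independently, while the estimated correlation of the real lists reached 0.871, in the Kupffer cell list. The simulation therefore does not tell how often camera with the preset correlation calls unshifted lists of correlated genes. Library pairs within a group differed by a chi-square of 26.9 to 153.6 per degree of freedom, so that none were duplicates. The labels give the same replicate numbers to both groups and no shared litter or batch, so the number was used as a block only in an alternative. The alternatives were other scalings, including DESeq2 1.42.0 size factors, other filters, the DESeq2 and limma-voom tests, a non-robust dispersion, a test against a fold change of 1.2, a threshold of 0.01, the replicate block, sex as a term, leaving out each library, and, added after the data were seen, leaving out both female libraries. Labels do not tell the kinds of control apart, so these were not compared.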

Results

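Liver RNA was profiled from adult mice of 8 to 10 weeks of age by stranded poly(A) RNA sequencing, in 4 libraries labelled WT and 4 labelled CAPZ_KO. In the CAPZ_KO animals tamoxifen, first given at an age of 4 to 6 weeks, activates a Cre recombinase that is expressed from the albumin promoter in hepatocytes and removes part of floxed Capzb, the gene of the beta subunit of the actin capping protein. Controls were of 2 kinds, floxed animals without Cre that were injected and animals with Cre that were not, and the labels do not say which WT library is which. Exposure to tamoxifen may therefore differ between the groups, and in no result below can this be told apart from the deletion. The replicates are separate samples in the labels, which do not state that each is a separate animal, so that p-values measure the spread between these samples. Total counts per library ranged from 12060350 to 18916315 in WT and from 13122355 to 16984971 in CAPZ_KO. The series asks how control of actin filaments bears on organ growth and on the maintenance of cell fate, and its comparison is CAPZ_KO against WT liver.

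Capzb, scaled by TMM, was lower in every CAPZ_KO library than in any WT library. It stood at 120.2 ± 13.4 CPM (read counts scaled to library size, SD, n = 4) in WT and at 72.5 ± 6.80 (SD, n = 4) in CAPZ_KO, which is 60.3% of the WT level. The WT libraries held 139.6, 109.4, 117.7 and 113.8 CPM and the CAPZ_KO libraries 69.4, 79.6, 64.5 and 76.4 CPM. The log2 fold change was −0.73 ± 0.125 (SE), with an adjusted p of 0.00134 by edgeR. An exact two-sided permutation test of log2(CPM + 1) gave a difference of −0.72 and p = 0.0286, the smallest that the 70 arrangements of 4 against 4 libraries allow. Capzb lies on chromosome 4 from 139192899 to 139291818 (plus strand, GRCm38), and its counts cover the whole gene, deleted part and remainder together. The genes of the alpha subunits, Capza1 and Capza2, had log2 fold changes of 0.45 ± 0.194 (SE) and 0.19 ± 0.154 (SE), with edgeR adjusted p of 0.0876 and 0.36. Capza3, the alpha subunit of male germ cells, had too few counts to be tested. Scaled by library sizes alone, Capzb had an edgeR log2 fold change of −0.10 with an adjusted p of 0.442, Capza1 had 1.07 and Capza2 0.80 (adjusted p = 0.00182 and 0.0018), and that scaling moved the median of all tested genes by 0.622, so that Capzb lay at −0.726 relative to it.

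**Figure D1:**
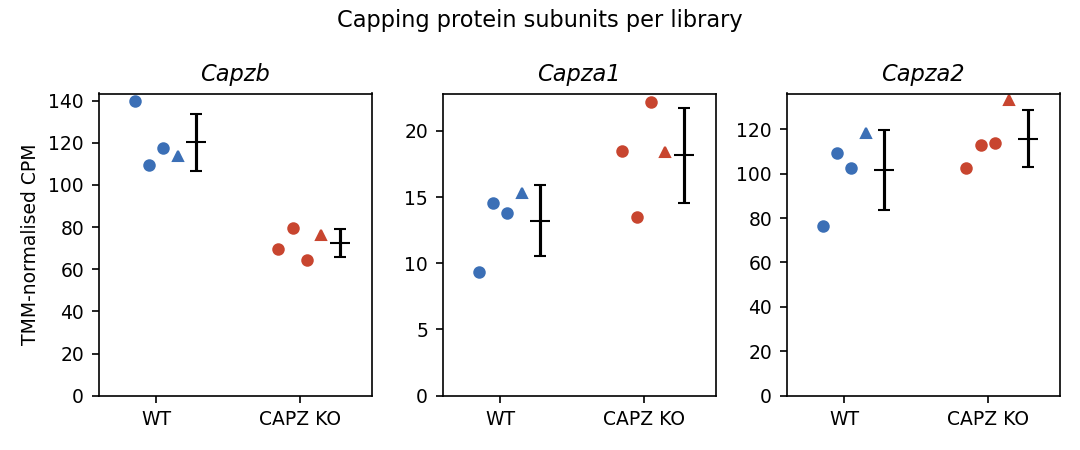
Normalised read counts (TMM-normalised CPM) of the capping protein subunit genes in each library, with circles for male and triangles for female libraries, a horizontal bar for the mean and whiskers for the SD (n = 4). The 4 CAPZ_KO libraries lie between 64.5 and 79.6 CPM of Capzb, all below the WT libraries, and the groups overlap for Capza1 and Capza2.

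Of 12985 genes tested, 2913 were higher and 2469 lower in CAPZ_KO at an adjusted p under 0.05 by edgeR, which is 41.4% of them. By at least 2-fold, 1825 were higher and 922 lower. All 4 libraries of 1 group lay above all 4 of the other in 40.3% of tested genes, against 2.86% by chance. Libraries correlated at 0.950 to 0.974 within WT, at 0.958 to 0.981 within CAPZ_KO and at 0.870 to 0.917 between the groups (Pearson's r across genes, which are not independent replicates). The abundant secreted proteins took different shares of the counts. Alb, the albumin gene, took 11.8% ± 2.14 (SD, n = 4) of all counts in WT and 4.28% ± 0.668 (SD, n = 4) in CAPZ_KO, and its log2 fold change was −2.08 ± 0.214 (SE, edgeR adjusted p = 8.14e-05). Of the other genes with the largest mean CPM, Serpina3k and Apoe had log2 fold changes of −3.05 and −0.60 (edgeR adjusted p = 0.000275 and 0.014), while Trf, Ahsg and Hpx had adjusted p of 0.871, 0.461 and 0.425. Under library sizes alone 7665 genes were higher and 700 lower, so that 91.6% of calls were higher against 54.1% with TMM, and Apoe had a log2 fold change of 0.016.

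**Figure D2:**
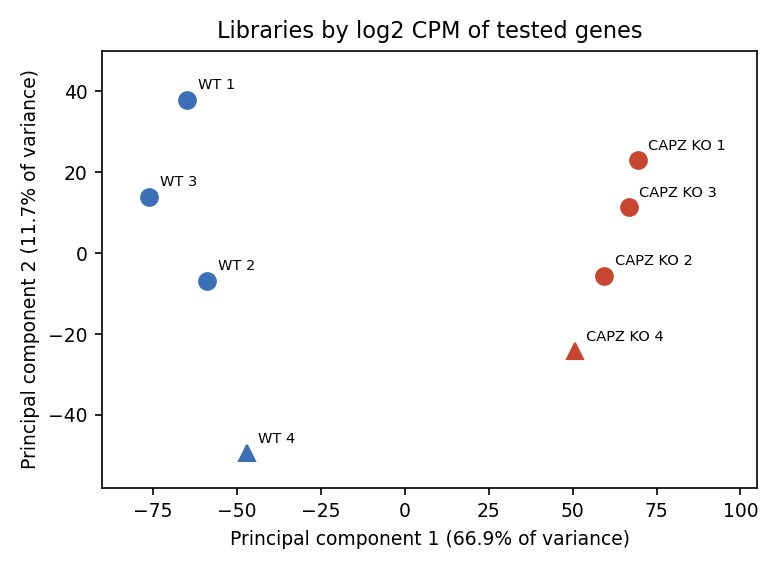
Principal components of log2 CPM over the tested genes, with component 1 (66.9% of the variance) on the horizontal and component 2 (11.7%) on the vertical axis, 1 point per library, circles for male and triangles for female libraries. The groups lie apart on component 1, and the female library of each group has the lowest value of its group on component 2.

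The genes with the largest rises included several that are nearly silent in WT liver. H19, an imprinted long noncoding RNA of fetal liver on chromosome 7 (142575529 to 142578143, minus strand), had 1 count over the WT libraries, in WT 1, and 933 over the CAPZ_KO libraries, a ratio of 643.3 with a 95% counting interval from 115.2 to 25440. Ly6d (chromosome 15, 74762056 to 74763620), a surface protein, was at 1.71 ± 0.820 CPM in WT and 283.4 ± 120.4 in CAPZ_KO (SD, n = 4), a log2 fold change of 7.35 ± 0.491 (SE). Sprr1a, a cornified envelope protein, rose by 8.32 ± 1.14 (SE) to 137.0 ± 97.7 CPM (SD, n = 4). Gsta1, a glutathione S-transferase, rose by 6.92, Tubb2b, a beta tubulin, by 6.87, and Nrg1, a ligand of ErbB receptors, by 6.59. Wfdc3, Gipc2, Shc2 and Spink1 rose by 7.06, 6.95, 6.46 and 6.34. Without WT 4 the values of Sprr1a, Gipc2 and Tubb2b were 10.63, 8.58 and 7.71, and Tubb2b was at 6.07 without CAPZ_KO 3. All of these passed at an edgeR adjusted p of 0.000881 or less.

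Of the 10 genes with the largest falls, Mup7, Mup12, Slco1a1, Serpina1e and Elovl3 are in the list of liver genes higher in males and Cyp3a44 is in that of genes higher in females (male- and female-predominant genes). Sult2a8, a sulfotransferase (chromosome 7, 14410686 to 14446769), fell from 1068 ± 398.8 to 1.05 ± 0.187 CPM (SD, n = 4), a log2 fold change of −9.98 ± 0.366 (SE, edgeR adjusted p = 4.69e-07). Cyp8b1, the sterol 12-alpha-hydroxylase of bile acid synthesis (chromosome 9, 121914356 to 121916305), fell from 205.7 ± 36.0 to 1.65 ± 0.721 CPM (SD, n = 4), and Cyp2c69 had a log2 fold change of −6.56 ± 0.443 (SE). Mup3, a major urinary protein, had −7.77 ± 0.861 (SE), and without CAPZ_KO 1 it had −8.38. The other 6 had WT SDs close to or above their WT means. Mup7 had −13.37 ± 3.32 (SE, edgeR adjusted p = 0.015), with 4048 CPM in WT 3 and 1.36 to 42.6 in the other WT libraries, and had −7.92 without WT 3. Its adjusted p was 0.05, 0.0503 and 0.0553 without CAPZ_KO 2, 3 and 4, and 0.243 by limma-voom. Slco1a1 had −9.89 ± 1.85 (SE), −9.22 without WT 3 and −10.93 without CAPZ_KO 1, and Serpina1e had −7.89 ± 1.46 (SE) and −7.12 without WT 3. Elovl3 had −7.75 ± 1.47 (SE), −6.91 without WT 1 and −8.81 without CAPZ_KO 4, and the limma-voom adjusted p was 0.122 for Slco1a1 and 0.0755 for Elovl3. Mup12 had −7.56 ± 1.61 (SE), −5.65 without WT 3 and −8.16 without CAPZ_KO 3. Cyp3a44 had −6.40 ± 1.70 (SE, edgeR adjusted p = 0.0196) and −3.51 without WT 4, the female WT library, and its adjusted p was 0.0567 to 0.0624 when any CAPZ_KO library was left out and 0.123 by limma-voom. Mup, Serpina1, Cyp2c, Cyp3a and Gsta genes belong to families of near-identical copies, so that the division of reads among their members is uncertain.

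**Figure D3:**
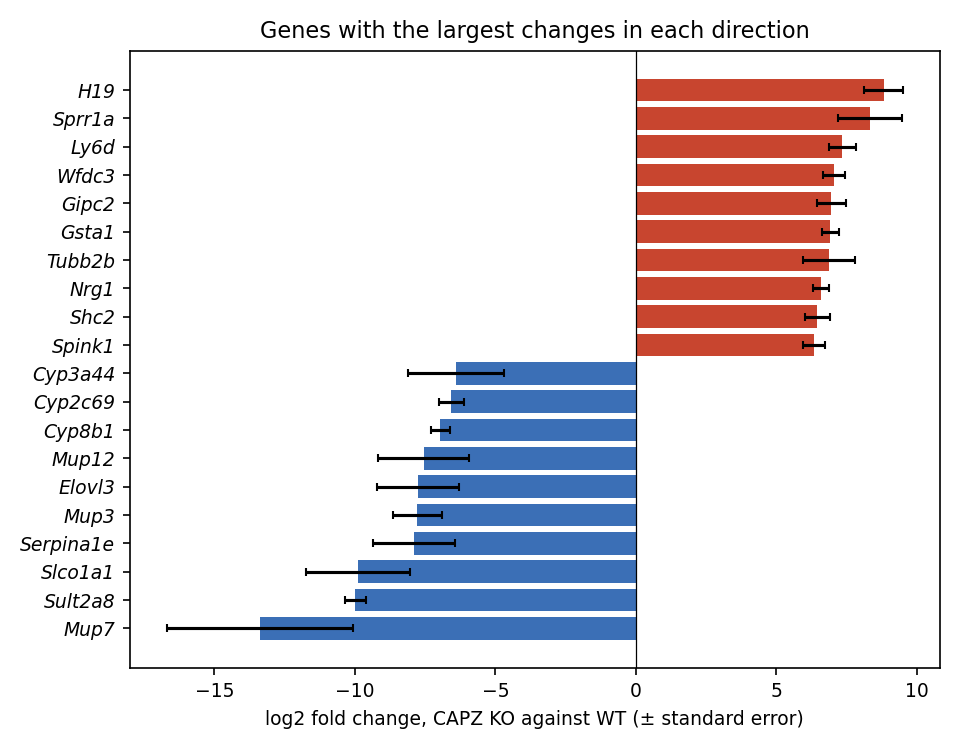
Log2 fold change of CAPZ_KO against WT (horizontal axis) with its standard error for the 10 genes with the largest change in each direction by the fixed rule. Mup7 lies lowest at −13.37 with the widest error of ± 3.32, and the value of H19 rests on 1 WT count and is no estimate of its fold.

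Genes of the actin cytoskeleton rose together. Of 29 tested targets of the actin-regulated transcription factors SRF and MRTF and genes of the cytoskeleton, 28 rose and 0 fell, with a median log2 fold change of 1.81 (28 rose when adjusted over the list alone, camera adjusted p = 5.07e-13, and adjusted p = 0.138 with an estimated correlation). Tagln2, an actin-binding protein, rose by 3.26 ± 0.212 (SE), Tes, a focal adhesion protein, by 4.27 ± 0.335 (SE), and Myl12a, a myosin light chain, by 1.93, while Tpm1, a tropomyosin, rose from 36.4 ± 4.94 to 206.2 ± 54.6 CPM (SD, n = 4). Among 20 genes of actin capping and of the barbed end of filaments, 9 rose and Capzb fell (10 and 1 adjusted over the list alone, median 0.71, camera adjusted p = 0.00179, and adjusted p = 0.138 with an estimated correlation). Capg, a capping protein of the gelsolin family, rose by 2.28, Add1, an adducin, by 0.96 and Vasp, which promotes filament elongation, by 1.13. Of 21 targets of the growth regulators YAP and TAZ, 15 rose and 0 fell (15 adjusted over the list alone, median 0.68, camera adjusted p = 0.000105, and adjusted p = 0.147 with an estimated correlation). Cyr61, a matricellular protein, rose by 3.32 ± 0.294 (SE) from 7.02 ± 2.32 to 69.5 ± 21.8 CPM (SD, n = 4), Tgfb2 by 4.33, Myof by 2.15 and Ankrd1, chosen after its values were seen, by 5.24. Ctgf, chosen likewise, was at 15.9 ± 3.72 CPM in WT and 23.0 ± 2.12 in CAPZ_KO (SD, n = 4), with an edgeR adjusted p of 0.0284 that became 0.0511 to 0.0765 when any library but WT 3 was left out. Of 11 Notch pathway genes, 6 rose, with Hes1 at 1.88 and Hey1 at 2.26, and Hes6, chosen after its values were seen, fell by 1.34 (6 and 1 adjusted over the list alone, median 0.64, camera adjusted p = 0.0271, and adjusted p = 0.139 with an estimated correlation). Scaled by library sizes alone the Notch list had a camera adjusted p of 0.155 and Hes6 an edgeR adjusted p of 0.117. In the same libraries the marker list of hepatocytes had a median of −1.39 and those of monocyte-derived macrophages and stellate cells 2.24 and 1.18.

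**Figure D4:**
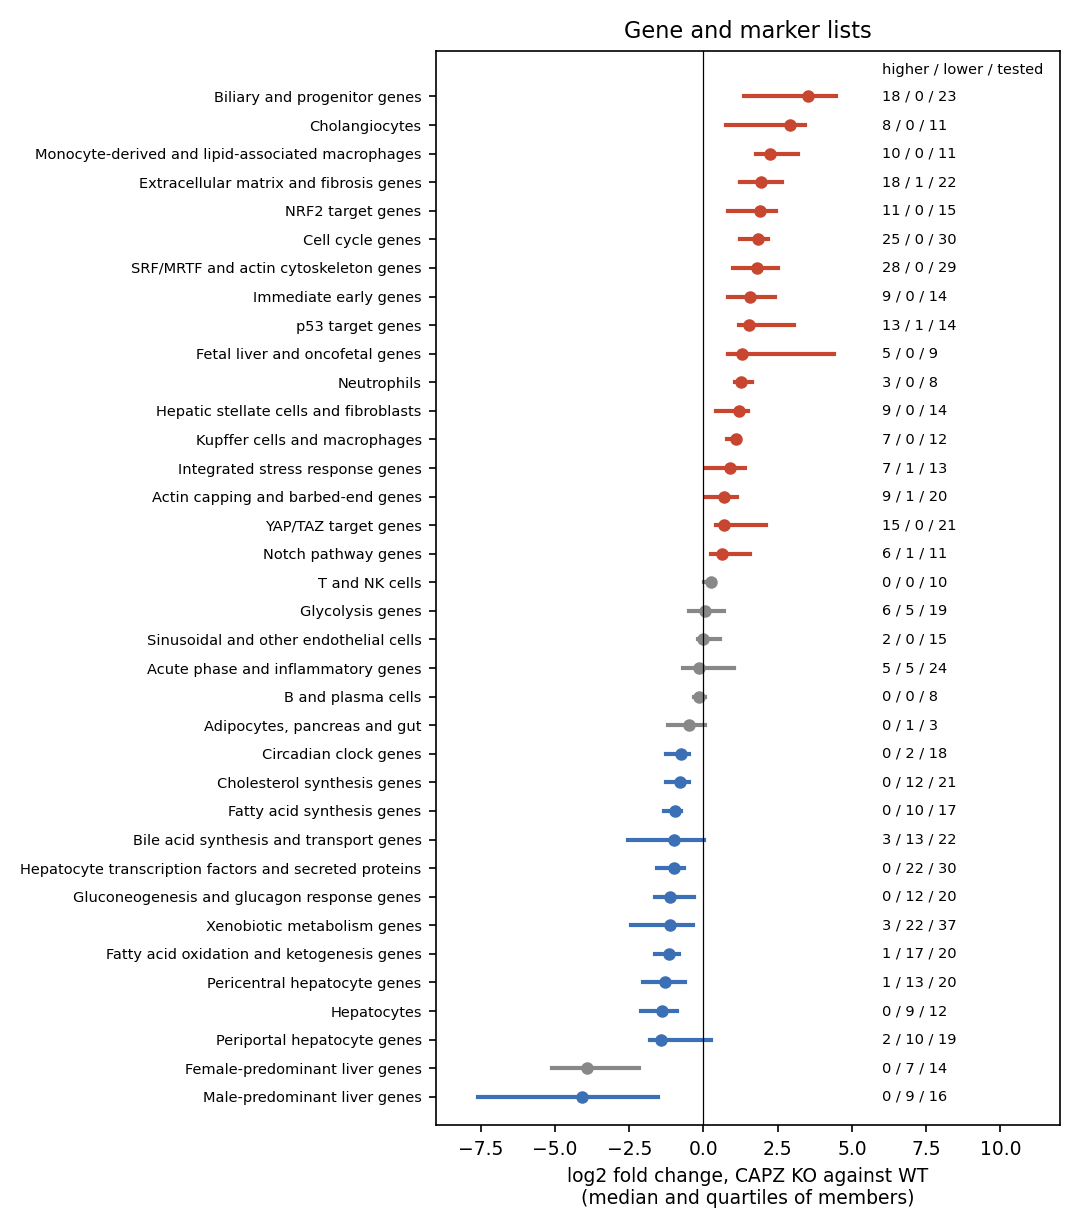
Median (point) and quartiles (line) of the log2 fold changes, CAPZ_KO against WT, of the members of each of the 36 tested lists, with the numbers of members higher, lower and tested at the right. Red and blue mark the 17 lists called higher and the 12 called lower by camera with a preset correlation, grey the others. Under library sizes alone, which moves the median of all genes by 0.622, the acute phase median turns from −0.14 to 0.47.

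Biliary, fetal or oncofetal, and proliferation genes rose. Marker lists of cholangiocytes, monocyte-derived macrophages and stellate cells also rose (medians 2.92, 2.24 and 1.18), while those of endothelial, T, NK and B cells were not called. The counts do not tell in which cells the genes rose. Of 23 biliary and progenitor genes, 18 rose and 0 fell, with a median log2 fold change of 3.53 (20 adjusted over the list alone, camera adjusted p = 3.15e-08, and adjusted p = 0.146 with an estimated correlation). Spp1, osteopontin, rose by 4.32 from 30.2 ± 5.25 to 603.9 ± 321.1 CPM (SD, n = 4), Prom1, a membrane glycoprotein of progenitor cells, by 4.71, Elf3, an epithelial transcription factor, by 4.72, and Sox9, a transcription factor of bile duct cells, by 3.62 ± 0.406 (SE). Some biliary markers chosen after their values were seen did otherwise. The biliary keratins Krt7 and Krt19 had log2 fold changes of −0.01 ± 0.535 and −0.23 ± 0.460 (SE, edgeR adjusted p = 0.994 and 0.713), while Epcam, an epithelial adhesion molecule, rose from 1.04 ± 0.309 to 8.30 ± 3.14 CPM (SD, n = 4, edgeR adjusted p = 0.000179). Krt8 and Krt18, keratins that hepatocytes also express, rose by 3.12 and 2.91. The list of fetal liver and oncofetal genes held 13 members, of which 9 had enough counts to be tested. Of these 9, 5 rose and 0 fell (6 adjusted over the list alone, median 1.29, camera adjusted p = 9.5e-04, and adjusted p = 0.139 with an estimated correlation). Tspan8 rose by 4.41, besides H19 and Ly6d. Igf2, a fetal growth factor, rose by 2.79 from a mean of 0.316 to 2.12 CPM. Afp, alpha-fetoprotein, rose by 1.29 from 3.07 to 7.47 CPM, and Gpc3 had −0.32 with an edgeR adjusted p of 0.611. Afp and Gpc3 were chosen after their values were seen. The median of this list was 2.32 without WT 1 and 2.35 without CAPZ_KO 4. Of 30 cell cycle genes, 25 rose and 0 fell (26 adjusted over the list alone, median 1.82, camera adjusted p = 8.95e-06, and adjusted p = 0.311 with an estimated correlation). Mcm2, Mcm5 and Mcm6, subunits of the replicative helicase, rose by 2.03, 2.10 and 1.98.

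Targets of p53 and genes of stress responses rose in the same livers. The marker list of hepatocytes had a median of −1.39 there, and those of monocyte-derived macrophages and stellate cells 2.24 and 1.18, so that the cells behind these rises are not known. Of 14 targets of p53, 13 rose, and Ei24 fell by 0.48 (13 and 1 adjusted over the list alone, median 1.55, camera adjusted p = 1.71e-06, and adjusted p = 0.139 with an estimated correlation). Phlda3 rose by 4.23 ± 0.275 (SE), Eda2r by 4.09, Zmat3 by 2.17 and Cdkn1a, the cyclin-dependent kinase inhibitor p21, by 4.71, with 5.33 without WT 1. Cdkn1a and Ei24 were chosen after their values were seen, and Ei24 had an edgeR adjusted p of 0.0532 without CAPZ_KO 3 and a log2 fold change of 0.14 with library sizes alone. Of 15 targets of the antioxidant regulator NRF2, 11 rose and 0 fell (12 adjusted over the list alone, median 1.92, camera adjusted p = 6.85e-07, and adjusted p = 0.105 with an estimated correlation). Gstm3, a glutathione S-transferase, rose by 4.76 from 131.3 ± 51.0 to 3568 ± 462.7 CPM (SD, n = 4), and Srxn1, sulfiredoxin, by 2.64. Of 14 immediate early genes, 9 rose and 0 fell (10 adjusted over the list alone, median 1.57, camera adjusted p = 4.06e-04, and adjusted p = 0.147 with an estimated correlation), with Jun at 2.43 and Klf6 at 2.64. Of 13 genes of the integrated stress response, 7 rose and Cebpb fell by 1.14 (7 and 1 adjusted over the list alone, median 0.88, camera adjusted p = 0.0287, and adjusted p = 0.266 with an estimated correlation), with Atf3 at 3.32 and Gdf15 at 2.11. That list had a camera adjusted p of 0.0742 without WT 2 and of 0.301 under library sizes alone, where the edgeR adjusted p of Cebpb was 0.0568.

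Genes of mature hepatocyte function fell. The marker list of hepatocytes fell as well (median −1.39), and the lists given here were not tested apart from it. Of 30 hepatocyte transcription factor and secreted protein genes, 22 fell and 0 rose (22 adjusted over the list alone, median −0.99, camera adjusted p = 1.51e-09, and adjusted p = 0.105 with an estimated correlation). Ttr, transthyretin, fell from 9319 ± 1760 to 2105 ± 252.9 CPM (SD, n = 4), and F9, coagulation factor IX, had a log2 fold change of −1.21. Of 20 pericentral genes, which are expressed near the central vein, 13 fell and Slc1a4 rose by 2.48 (15 and 1 adjusted over the list alone, median −1.30, camera adjusted p = 4.3e-06, and adjusted p = 0.139 with an estimated correlation). Cyp2e1 had a log2 fold change of −3.83 ± 0.351 (SE), Rgn of −2.65 and Glul, glutamine synthetase, of −2.08. Of 19 periportal genes, 10 fell, and Hsd17b13 and Aldh1b1 rose by 1.05 and 0.99 (12 lower and 4 higher adjusted over the list alone, median −1.42, camera adjusted p = 0.00776, and adjusted p = 0.389 with an estimated correlation). Gls2, liver glutaminase, had −2.31 and Hal, histidine ammonia lyase, −2.38. Slc1a4, Glul, Hsd17b13 and Aldh1b1 were chosen after their values were seen. Both zones of the liver lobule therefore held genes that fell, and no test of a difference between zones was made. Other lists also hold 7 of the 30 transcription factor and secreted protein genes, 3 of the pericentral and 3 of the periportal genes. The falls of these lists are therefore not fully separate evidence.

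Genes of metabolic pathways of the liver fell with them, and were likewise not tested apart from the hepatocyte markers (median −1.39). Other lists also hold 5 of the xenobiotic metabolism genes tested and 5 of the bile acid genes. Of 37 xenobiotic metabolism genes, 22 fell, and Gstm1, Ephx1 and Fmo5 rose by 1.63, 1.24 and 1.16 (23 lower and 4 higher adjusted over the list alone, median −1.13, camera adjusted p = 2.09e-06, and adjusted p = 0.139 with an estimated correlation). Cyp2c29, Cyp2c54 and Cyp2c50 had log2 fold changes of −3.38, −4.48 and −2.71. Fmo5 had an edgeR adjusted p of 0.0616, 0.0524 and 0.057 without WT 1, WT 2 and CAPZ_KO 4. Of 22 bile acid genes, 13 fell, and Abcb4, Abcc4 and Slc51b, which export phospholipid, organic anions and bile acids, rose by 0.53, 2.14 and 3.42 (14 lower and 3 higher adjusted over the list alone, median −0.98, camera adjusted p = 1.73e-04, and adjusted p = 0.138 with an estimated correlation). Slc10a1, the bile acid uptake carrier, had −3.59 ± 0.243 (SE), Slco1b2 −2.69 and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, −2.99. Abcb4 had an edgeR adjusted p of 0.0578 to 0.089 when WT 1, WT 3 or CAPZ_KO 1, 2 or 3 was left out, and Abcc4 was at 2.73 without WT 4. Of 20 genes of fatty acid oxidation and ketogenesis, 17 fell (18 lower and 1 higher adjusted over the list alone, median −1.16, camera adjusted p = 1.56e-07, and adjusted p = 0.146 with an estimated correlation), with Acaa2, a thiolase of mitochondrial beta-oxidation, at −1.34 and Acadvl, the very long chain acyl-CoA dehydrogenase, at −1.19. The member that rose was Fgf21, a hormone, at 2.70 with an edgeR adjusted p of 0.0437 that became 0.0643 to 0.12 without WT 2, WT 3 or CAPZ_KO 1, 3 or 4. Gstm1, Ephx1, Fmo5, Abcb4, Abcc4, Slc51b, Cyp7a1 and Fgf21 were chosen after their values were seen.

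Lipid and glucose synthesis genes also fell, and were not tested apart from the hepatocyte markers (median −1.39) either. Other lists also hold 3 of the genes of gluconeogenesis and the glucagon response. Of 17 fatty acid synthesis genes, 10 fell and 0 rose (11 adjusted over the list alone, median −0.96, camera adjusted p = 1.82e-05, and adjusted p = 0.158 with an estimated correlation), with Mlxipl, a carbohydrate-responsive transcription factor, at −2.22. Of 21 cholesterol synthesis genes, 12 fell and 0 rose (15 adjusted over the list alone, median −0.79, camera adjusted p = 2.87e-05, and adjusted p = 0.29 with an estimated correlation), with Nsdhl at −1.26, Msmo1 at −1.20 and Idi1 at −1.35. Of 20 genes of gluconeogenesis and the glucagon response, 12 fell and 0 rose (12 adjusted over the list alone, median −1.12, camera adjusted p = 6.54e-05, and adjusted p = 0.29 with an estimated correlation). G6pc, glucose-6-phosphatase, had −4.49 ± 0.759 (SE), and −5.19 without CAPZ_KO 4, Fbp1 had −1.63 and Gcgr, the glucagon receptor, −0.78. Under library sizes alone, the edgeR adjusted p of Gcgr was 0.347. Glycolysis genes went both ways, with 6 of 19 higher and 5 lower (6 and 5 adjusted over the list alone, median 0.06, camera adjusted p = 0.697, and adjusted p = 0.742 with an estimated correlation). Pkm, the pyruvate kinase of most tissues other than liver, and Hk2, a hexokinase low in hepatocytes, rose by 1.40 and 1.38, and Pklr, the liver pyruvate kinase, fell by 1.55. Other members that fell, chosen after their values were seen, were Pfkm, Pgk1 and Pfkfb3, at −0.70, −0.44 and −1.22.

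Matrix genes and markers of several nonparenchymal cells rose. Of 22 extracellular matrix and fibrosis genes, 18 rose, and Fn1, fibronectin, which hepatocytes also secrete, fell by 0.57 (18 and 1 adjusted over the list alone, median 1.95, camera adjusted p = 3.15e-08, and adjusted p = 0.139 with an estimated correlation). Col4a1 rose by 2.06, Loxl2, a collagen cross-linking enzyme, by 2.74, and Col1a1, a fibrillar collagen, by 3.13, with 3.78 without WT 1. Col1a1 and Fn1 were chosen after their values were seen, and Fn1 had an edgeR adjusted p of 0.0524 without WT 2 and of 0.05 without CAPZ_KO 3, and a log2 fold change of 0.054 with library sizes alone. Of 14 stellate cell and fibroblast markers, 9 rose and 0 fell (9 adjusted over the list alone, median 1.18, camera adjusted p = 7.51e-04, and adjusted p = 0.139 with an estimated correlation), with Lum, a matrix proteoglycan, at 2.28 and Lrat, which esterifies retinol in stellate cells, at 1.78. Of 11 markers of monocyte-derived and lipid-associated macrophages, 10 rose and 0 fell (10 adjusted over the list alone, median 2.24, camera adjusted p = 1.87e-05, and adjusted p = 0.139 with an estimated correlation), with Cx3cr1 at 3.59, Cd9 at 2.24 and Trem2 at 3.28, or 4.04 without WT 4. Of 12 Kupffer cell and macrophage markers, 7 rose and 0 fell (8 adjusted over the list alone, median 1.09, camera adjusted p = 0.00179, and adjusted p = 0.426 with an estimated correlation), with C1qa at 1.02 and Cd68 at 1.32. Of 11 cholangiocyte markers, 9 of which another list also holds, 8 rose and 0 fell (9 adjusted over the list alone, median 2.92, camera adjusted p = 6.54e-05, and adjusted p = 0.158 with an estimated correlation), with Tm4sf4 at 2.30. Of 8 neutrophil markers, 3 rose and 0 fell (4 adjusted over the list alone, median 1.27, camera adjusted p = 0.0166, and adjusted p = 0.426 with an estimated correlation). They were Csf3r, Mmp8 and Cxcr2, at 10.04, 1.23 and 1.31 CPM in CAPZ_KO. Their edgeR adjusted p became 0.0505 for Csf3r without CAPZ_KO 2, 0.0525 to 0.0585 for Mmp8 without WT 2, WT 3 or CAPZ_KO 4, and 0.0603 to 0.116 for Cxcr2 without any library but WT 4. Under library sizes alone the camera adjusted p was 0.0599 for the Kupffer cell list and 0.246 for the neutrophil list.

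Hepatocyte markers fell, and the marker lists of endothelial, T, NK and B cells and of adipocytes, pancreas and gut were not called. Of 15 endothelial markers, Pecam1 and Cdh5 rose and 0 fell (1 adjusted over the list alone, median −0.01, mean 0.15, camera adjusted p = 0.735, and adjusted p = 0.89 with an estimated correlation). Pecam1 rose by 0.56, and Cdh5 had 0.75 with an edgeR adjusted p of 0.0451 that became 0.0502 to 0.112 without WT 1, 3 or 4 or CAPZ_KO 2, 3 or 4. None of 10 T and NK cell markers or 8 B cell markers passed at an adjusted p under 0.05 by edgeR, over all genes or adjusted over the list alone (medians 0.24 and −0.15, camera adjusted p = 0.502 and 0.832, and adjusted p = 0.842 and 0.929 with an estimated correlation), and 0 of them had an unadjusted p under 0.05, the smallest being 0.0631 for Lck. Of 12 hepatocyte markers, 8 of which another list also holds, 9 fell and 0 rose (9 adjusted over the list alone, median −1.39, camera adjusted p = 5.2e-06, and adjusted p = 0.139 with an estimated correlation). Of 3 tested markers of adipocytes, pancreas and gut, Cela1 fell by 1.91 (1 adjusted over the list alone, median −0.48, camera adjusted p = 0.471, and adjusted p = 0.66 with an estimated correlation). Only Alas2 of the erythroid list had enough counts, and it fell by 2.82, or by 2.16 without WT 3.

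Inflammatory genes went both ways, and circadian clock genes were lower as a list. Of 24 acute phase and inflammatory genes, 5 rose and 5 fell (5 and 5 adjusted over the list alone, median −0.14, mean 0.09, camera adjusted p = 0.722, and adjusted p = 0.89 with an estimated correlation). Ccl2, a monocyte chemokine, rose by 2.99, Icam1, an adhesion molecule, by 1.47, and Lcn2, lipocalin 2, chosen after its values were seen, by 3.82 ± 0.720 (SE), and Tnf and Il1b by 1.58 and 0.99, while Crp, Itih4, Orm1 and Fgl1, secreted by hepatocytes, had −1.53, −1.48, −0.75 and −0.98. Saa1 had −2.62 (edgeR adjusted p = 0.0406), with 2088 CPM in WT 1 and 151.2 to 257.7 in the other WT libraries, had −0.98 without WT 1, and had an adjusted p of 0.0793 to 0.106 when any CAPZ_KO library was left out. Tnf, Il1b, Orm1, Fgl1 and Saa1 were chosen after their values were seen. Scaled by library sizes alone, the list's median was 0.47 and its camera adjusted p 0.0233. Camera then called the list lower, because it compares a list with the other genes, and the median of all tested genes was 0.622. Of 18 circadian clock genes, Hlf and Bhlhe41 fell and 0 rose (1 lower adjusted over the list alone, median −0.75, camera adjusted p = 0.0425, and adjusted p = 0.326 with an estimated correlation). The camera adjusted p was 0.0833, 0.0688, 0.0754 and 0.0516 without WT 3, WT 4, CAPZ_KO 1 and CAPZ_KO 3. Hlf fell by 1.65, and Bhlhe41 had −2.66 with an edgeR adjusted p of 0.0265 that became 0.0501 to 0.074 without WT 2, WT 3 or CAPZ_KO 1, 2 or 4.

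Among liver genes that differ between the sexes, members that favour either sex fell in the test of all 8 libraries together, but the groups overlapped. The mean log2 CPM of the female-predominant genes was 0.674 in WT 3, against 1.04 to 2.30 in CAPZ_KO. That of the male-predominant genes was 2.23 in WT 4, against 2.15 to 3.26 in CAPZ_KO. Counts of Xist, the RNA of the inactive X chromosome, were 5419 in WT 4 and 4067 in CAPZ_KO 4 and at most 6 elsewhere, while the Y-linked Ddx3y was at 0 in these libraries and at 342 to 1180 in the others, so that each group held 1 female and 3 male libraries. Of 16 male-predominant genes, 9 fell and 0 rose (12 adjusted over the list alone, median −4.08, camera adjusted p = 0.0199, and adjusted p = 0.63 with an estimated correlation), and fry gave an adjusted p of 0.251. C8b, a complement component, fell by 2.25 ± 0.403 (SE). The median of this list was −3.03 without WT 3, −4.89 without WT 4 and −5.12 without CAPZ_KO 1. Of 14 female-predominant genes, 7 fell and 0 rose (7 adjusted over the list alone, median −3.91, camera adjusted p = 0.0534, and adjusted p = 0.651 with an estimated correlation), and fry gave 0.343. Its camera adjusted p was 9.17e-04 with sex as a term, 1.27e-04 with the replicate block, 1.27e-06 with library sizes alone, 0.024 with upper quartile scaling, 0.0143 with no filter, and 0.0474, 4.25e-04 and 0.0412 without WT 1, WT 3 and CAPZ_KO 4. Without WT 4, the female WT library, its median was −1.83 with a camera adjusted p of 0.234. Without both female libraries, a test added after the data were seen, its median was −1.77 (camera adjusted p = 0.15) and that of the male-predominant list −4.88 (camera adjusted p = 7.03e-07). Cyp17a1, a steroid hydroxylase, had −3.77 ± 0.919 (SE) and −2.25 without WT 4. In WT the female library differed from the mean of the male libraries by a median of −4.73 over the male-predominant genes and of 4.68 over the female-predominant genes on the log2 scale. In CAPZ_KO these differences were 0.05 and 0.33. From WT to CAPZ_KO the male-predominant genes changed by a median of −4.41 between male libraries and 0.45 between the female libraries, and the female-predominant genes by −1.25 and −5.23.

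**Figure D5:**
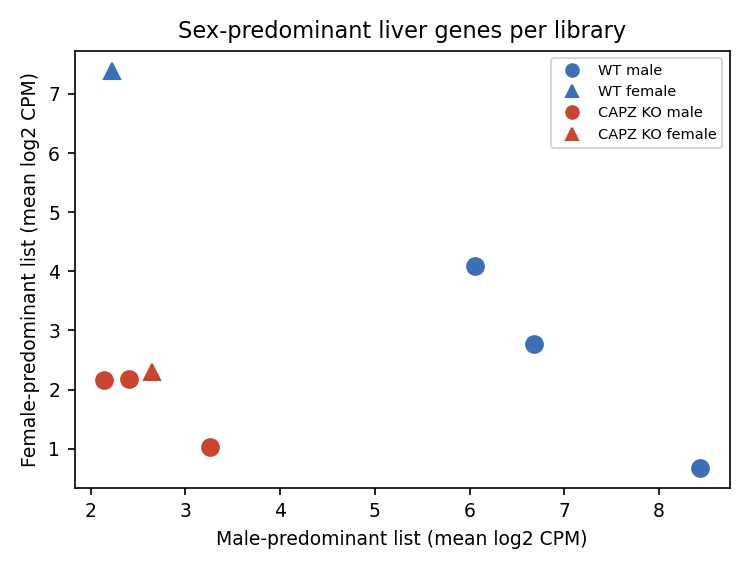
Mean log2 CPM of the male-predominant genes (horizontal axis) and the female-predominant genes (vertical axis) in each library, with circles for male and triangles for female libraries. The female WT library lies at 2.23 and 7.39. The male WT libraries lie between 6.06 and 8.43 on the horizontal and 0.674 and 4.09 on the vertical axis. The CAPZ_KO libraries lie between 2.15 and 3.26 on the horizontal and 1.04 and 2.30 on the vertical axis.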

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

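The tests on the Capzb level, on cell type and biliary markers, on the sex lists and by fry were chosen after the results were seen, while the counts of genes and of camera lists over other splits were planned. Single libraries stood far from the other 3 of their group in 28 of 490 group values tested, or 5.71%, where chance gives about 5%.

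In WT 1 these were H19 (0.107 CPM, the others at 0), Myl12a (90.9), Ttr (11930), Saa1 (2088 against 151.2 to 257.7), Col1a1 (17.7) and Slc1a4 (10.51). In WT 3 they were Mup7 (4048), Mup12 (35.1), Cyp7b1 (680.9) and, on the low side, the mean log2 CPM of the xenobiotic metabolism genes (8.44). In WT 4, the female library, they were Cyp3a44 (141.3), Cyp17a1 (284.5), Hao2 (22.6), Ccdc80 (24.8), Myof (9.85) and Cd8b1 (1.30), all high. In CAPZ_KO 1 they were Cd2ap (133.0), Acss2 (110.2), Klf6 (125.2) and Rspo3 (11.6) on the high side and, on the low side, Cyp2c69 (1.62) and the mean log2 CPM of the circadian clock (3.36) and female-predominant genes (1.04). In CAPZ_KO 2 Spink1 was high (17.8) and Notch3 low (1.25 CPM), and in CAPZ_KO 3 Trem2 was high (12.5). In CAPZ_KO 4 Fabp4 (26.9) and the mean log2 CPM of the glycolysis genes (5.90) were high.

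The counts of calls were set against the 35 splits of the 8 libraries into 4 and 4. For genes, 1 split, the real one, reached 5382 calls and the highest other called 0. That is the smallest share the 35 splits allow, so that chance is argued against but not excluded. Every other split mixes WT and CAPZ_KO libraries, which widens the spread within its groups and lowers its calls. For lists by camera, 2 of the 35 splits reached the real 29, and the highest other also called 29, so that chance cannot be excluded by that count. Splits that exchanged 1 library between the groups called 20 to 29 lists and those that exchanged 2 called 0 to 13, and the other split with 29 exchanged the female libraries, WT 4 and CAPZ_KO 4. By fry, 1 split reached 29 and the highest other called 1.

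The first pattern is the size of the Capzb fall. Capzb lay at −0.726 relative to the median of all genes (SE 0.115), but a scaling moves all genes alike, so that this value says nothing about the scaling. As a share of all counts, under library sizes alone, Capzb had −0.10 (p = 0.286 by exact permutation), which is no clear fall. The fall of −0.73 with TMM is relative to the other genes. Whether the absolute level of Capzb fell cannot be told apart from an effect of the scaling, because counts are relative to each other. Whether the remaining 60.3% of the Capzb level may come from cells that kept the gene, or from transcripts that lack the deleted part, cannot be told apart, because counts are per gene. Deletion in hepatocytes is what the design names, and its extent was not measured.

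The second pattern is the rise of markers of nonhepatocyte cells. A lower share of hepatocytes would raise the markers of all other cells alike. The monocyte-derived macrophage markers, 10 of whose 11 members WT liver also expresses at 1 CPM or more, rose above the endothelial markers by 2.37 on the log2 scale (exact permutation p = 0.0286). Stellate and Kupffer cell markers did so by 0.883 and 0.941 (exact permutation p = 0.0286 and 0.0571). This argues against an equal rise as the whole cause. These contrasts were picked after the list results were seen, 0.0286 is the smallest p possible, and the p-values were not adjusted for the contrasts. More cholangiocytes as the source of the biliary rise cannot be told apart from other sources. Krt7, Krt19 and Epcam, with a median of −0.00544 against a lower quartile of 2.77 of the other biliary genes, were picked after their values were seen and lay on both sides of it. Of 11 cholangiocyte markers 8 rose, but 9 of the 11 are also in the biliary and progenitor list, so that their rise is no separate evidence. A change within hepatocytes or a gain of particular cell types may account for the rest, and neither was tested.

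The third pattern is the fall of sex-predominant genes, where male-predominant genes changed by a median of −4.41 between male libraries and 0.451 between the female ones, and female-predominant genes by −1.25 and −5.23. Unequal sex of the animals is argued against by the balance of 1 female and 3 male libraries per group. With sex as a term 13 of the 16 called members stayed called. Because sex is balanced between the groups, that test could not have shown unequal sex and adds nothing to the balance. The mean of both lists together fell further than genes matched on WT level, by −2.17 (exact permutation p = 0.0286, the smallest possible). Neither list passed alone (−2.71 for male-predominant and −1.56 for female-predominant genes, exact permutation p = 0.143 and 0.4). The lists were taken up because of their fall, so that a general fall of genes of like abundance is not excluded as a part of the pattern. A smaller difference between female and male livers in CAPZ_KO may underlie it, but a test of the interaction per gene, run first, called 0 genes by edgeR, and fry, chosen after it, gave 0.0704 as the larger adjusted p of the male and female lists. With 1 female library per group this cannot be told apart from differences between single animals.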

How the results depend on the processing

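Tests with both female libraries left out were added after the data were seen. Of the gene counts, 2913 higher and 2469 lower became 7665 and 700 with library sizes alone, and 4251 against 2747 changed by at least 2-fold, because that scaling shifts the median of all genes by 0.622. Of 3627 genes called in both, 14 went the opposite way. A threshold of 0.01 gave 1864 and 1439, as fewer genes pass it. The other alternatives stayed within 1.5 times, among them 2371 to 2964 higher, 2100 to 2658 lower and 2560 to 2956 changed by at least 2-fold when single libraries were left out, and 2742 higher and 2108 lower without both female libraries. Lists called were 16 to 17 higher and 11 to 13 lower when single libraries were left out, and 0 higher and 0 lower by camera with an estimated correlation, which allows for correlated members. Capzb, with −0.80 to −0.65 when single libraries were left out, had −0.10 (p = 0.286 by exact permutation) with library sizes alone, −0.72 (p = 0.125 by exact sign flips, the smallest possible) as paired differences with the replicate block, and −0.77 (p = 0.1 by exact permutation, the smallest possible) without both female libraries. With library sizes alone Trf, Apoe, Ahsg, Fn1 and Ei24 reversed, at 0.58, 0.016, 0.46, 0.054 and 0.14. Of values of named genes under the alternatives, 3946 kept their side of the threshold and, where called, their direction, 118 lost the call, 32 gained it and 5 reversed. For lists by camera with the preset correlation these were 594, 9, 9 and 0. Medians of lists that were not called crossed 0, as the endothelial (−0.13 to 0.11), B cell (−0.50 to 0.25), T and NK cell (−0.09 to 0.43) and glycolysis (−0.0045 to 0.13) medians did when single libraries were left out, and that of adipocytes, pancreas and gut was 0.48 with no filter. Lists were not retested with DESeq2, limma-voom, the non-robust dispersion or the test against a fold. By deviations from the group means, libraries of the same replicate number correlated at r = 0.244, 0.0307, 0.0889 and 0.304 for the 4 pairs. Of the 8 libraries, 7 correlated best with their own number, and number 4 is the female library in both groups. A pairing by number is therefore possible, and the labels do not state one. The block gave 2974 genes higher and 2411 lower, with the female-predominant list called (camera adjusted p = 1.27e-04). In the simulation, with 50 genes changed by each of 4 folds, 22 of 50 2-fold changes were recovered. In the data 5382 genes were called, 2747 of them changed by at least 2-fold. With so many calls the adjusted threshold is less strict, so that the simulated recovery does not tell how many changes were missed.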

Other observations

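All tests in this part were chosen after the data were seen. Genes were grouped into 27 families by symbol, and each was tested for more higher or more lower calls than the 22.4% and 19% of all tested genes (Fisher's exact test, one-sided, adjusted over 54 tests). That test takes the genes of a family as independent, although members can move together. Its p-values count genes and do not measure the spread between libraries. The symbols taken as complex I were narrowed after a first run, to leave out assembly factors. Several families, some of them cytoskeletal or adhesion genes, held more higher calls. Of 11 tubulins, 9 were higher and 0 lower (adjusted p = 6.75e-04), with Tubb6 at a log2 fold change of 3.28 ± 0.346 (SE). Of 11 annexins, calcium-dependent membrane-binding proteins, 8 were higher (adjusted p = 0.00266), and Anxa5 rose from 101.3 ± 4.57 to 878.3 ± 140.9 CPM (SD, n = 4). Of 24 integrins, 14 were higher and 1 lower (adjusted p = 0.00138), with Itga6 at 1.65 and Itgax and Itgam, which are also markers of monocyte-derived macrophages (list median 2.24), at 2.05 and 1.79. Of 20 myosin heavy chain genes, 12 were higher (adjusted p = 0.00216), with Myh9, nonmuscle myosin IIA, at 2.01. Of 25 semaphorins and plexins, 14 were higher (adjusted p = 0.00213), and Plxna3 rose by 4.01. Of 11 TNF receptor family genes, 7 were higher (adjusted p = 0.0152), and Tnfrsf12a, the receptor of TWEAK, rose from 6.95 ± 1.66 to 143.5 ± 19.2 CPM (SD, n = 4). Medians of these families lay between 0.667 and 1.68, and under library sizes alone between 1.28 and 2.33. Collagens also held more higher calls (14 of 26, adjusted p = 0.00257), beside a rise of the stellate cell and fibroblast markers (median 1.18, 9 of 14 higher).

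Complex I and peroxin genes, among other families, held more lower calls, and these families were not tested apart from the hepatocyte markers, which also fell (median −1.39, 9 of 12 lower). Of 36 subunits of respiratory complex I, 30 were lower and 0 higher (Fisher's exact test, adjusted p = 6.43e-15), with Ndufb9 at −1.23 ± 0.176 (SE). Of 16 peroxins, which build peroxisomes, 15 were lower (adjusted p = 5.27e-09), with Pex6 at −0.99 (edgeR adjusted p = 0.0742 with library sizes alone). Their medians were −0.71 and −0.64, and with library sizes alone −0.0804 and −0.0189, so that they lay below the 0.622 shift of all genes under that scaling while their own values were near 0. Of 12 carboxylesterases 8 were lower (adjusted p = 0.00241), with Ces3b at −5.57, and of 18 serpins of clade A 11 were lower (adjusted p = 0.00105), with Serpina6, the corticosteroid-binding globulin, at −3.55. Of 74 ribosomal protein genes 3 were lower and 0 higher, and of 38 proteasome genes 6 were lower and 1 higher, with adjusted p of 1 in both directions. Their medians were −0.17 and −0.19, and 0.46 and 0.45 with library sizes alone. Cytochrome P450 2C and 4 genes, UDP-glucuronosyltransferases, organic ion carriers and complement components also held more lower calls, with adjusted p of 1.11e-05, 0.0277, 0.0045, 0.0165 and 0.0165. The symbols taken as complement left out C1qa, C1qb and C1qc, which rose by 1.02, 1.14 and 1.12 (edgeR adjusted p = 0.00116, 0.00176 and 0.00366). The result for complement therefore covers only the 10 other components taken. Claudins, S100 proteins, keratins, laminins, MHC genes, sulfotransferases, glutathione S-transferases and chemokines passed in neither direction.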
